A study of Mus musculus with 2 samples.

How the data were processed

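The series holds 2 mRNA sequencing libraries from mouse CD4 T cells, 1 from a culture labelled pathogenic Th17 and 1 from a culture labelled non-pathogenic Th17. Per the labels' protocols, polyadenylated RNA was captured on oligo(dT) beads, fragmented and copied from random primers, and the cDNA was size-selected and amplified by PCR. The labels do not describe a strand-marking step or molecular identifiers.

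The authors deposited a table of whole-number counts per gene and a table of FPKM values (fragment counts relative to transcript length and sequencing depth) for the same rows, each with 1 column per library, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the gene annotation are not given in the sources used here. The deposited tables hold 23702 rows, of which 10 are blank and 10 are overflowed annotation text. Of the remaining 23682 features, 22036 carry an Ensembl gene identifier and 1646 are numbered features with no gene name. The features with no gene name took 2.50% of counts in the pathogenic library and 2.90% in the non-pathogenic library and were left out of library sizes and ratios. Of the identifiers, 22022 were found in GENCODE release M21, whose assembly is the one named mm10, and 14 were not. In 27 rows the gene symbol had been turned into a calendar date, and these symbols were restored from the identifiers through GENCODE M21. Positions are from GENCODE M21, counted from base 1. For 19 symbols that stand on 2 identifiers, the identifier with more counts was used in the gene lists.

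Counts over named genes summed to 30877656 in the pathogenic library and 33470161 in the non-pathogenic library. Library sizes were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 1.00 in both libraries after rounding. The ratio of each gene was the log2 of CPM (counts relative to the scaled library size) in the pathogenic over the non-pathogenic library, with a prior count of 1 added in proportion to library size. Its 95% interval is the exact Clopper-Pearson interval of the binomial share of counts that fell in the pathogenic library. Because there was 1 library per condition, no test between conditions was made, no p-value was computed, and each ratio compares these 2 libraries. The intervals and the floors for a count of 0 cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Counts of 2 were 3.88 times as frequent among features as counts of 1 in the pathogenic library and 4.57 times as frequent in the non-pathogenic library. A sequenced fragment can therefore have added more than 1 to a count, and the intervals can be too narrow. Against a library with no count, the fold is a lower bound computed with a floor of 3 counts in that library.

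Genes with a mean of at least 1 CPM over both libraries were kept, which left 10597. A gene was listed as higher in a library at a ratio of at least 2-fold. The genes to name were chosen by a rule written before the data were examined. It takes the 12 highest and 12 lowest genes with a mean of at least 5 CPM, ranked by the bound of the interval nearest to a ratio of 1, leaving out predicted genes, pseudogenes and receptor segments. It adds 24 core Th17 genes whatever their value, and up to 4 genes with the largest ratios from each of 29 other gene lists. Some genes that the rule names are not reported here, though they stay in the counts and list medians. Those lists were also fixed before the data were examined. For each list with at least 3 measured members, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile among the random lists describes these libraries and is not a p-value. Genes of 1 pathway are co-regulated, so a list can leave the random range more easily than unrelated genes would. Some genes also stand in several lists, so the list medians are not separate results.

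The calculations were tested on simulated data, drawn for the real genes of this comparison from their mean levels and library sizes. The simulated counts held Poisson counting error only, with no variation between cultures or from PCR. Shares that rest on them check the calculations and are not error rates for the real libraries. Over 10600 simulated genes, the interval held the planted ratio for 95.4% of genes. All planted log2 ratios of 1.5, of which 49 genes passed the filter, and all 50 of 3 were recovered past 2-fold, as were the same sizes in the other direction. Of 10401 unchanged genes, 0.0192% passed. Among 200 unchanged lists of 15 genes, 7.5% fell outside the 95% random range. Of 20 lists of 15 real genes shifted by a log2 ratio of 0.3, 13 lay above the random range, and all 20 did with a shift of 0.6. A list inside the range can thus still hold a shift of that smaller size. The bar first set for the 0.3 shift was missed, and the larger shift was added after that.

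Alternatives fixed before the data were examined were total-count scaling, size factors of DESeq2 1.42.0, prior counts of 0.25 and 5, no filter, a filter at 5 CPM, ratios of the deposited FPKM values with 1 or 0.1 added before the log2, fold limits of 1.5 and 4, intervals wholly past 2-fold, and each list without its member of the largest ratio. Removal of a transcript length and GC trend, inclusion of features with no gene name, and omission of genes that overlap another gene on the same strand were added after the data were examined. The trend was a cubic fit of the log2 ratio on the length and GC share of each gene's longest protein-coding GENCODE M21 transcript, fitted on genes within a log2 ratio of 2 of the median. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.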

Results

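The transcriptomes of mouse CD4 T cells cultured toward pathogenic or non-pathogenic Th17 cells were compared, in a series concerned with Foxo1 and TGFβ1 in Th17 fate. Th17 cells are helper T cells that make IL-17. CD4 T cells from spleen and lymph node of wild-type mice were activated for 24 h on plates coated with anti-CD3 at 10 μg/mL and anti-CD28 at 5 μg/mL. The pathogenic condition received IL-6 at 20 ng/mL and activin A, a TGF-β family ligand, at 20 ng/mL. The non-pathogenic condition received IL-6 at 20 ng/mL and TGFβ1 at 2 ng/mL, so the conditions differed in the TGF-β family ligand. Antibodies to IFNγ and IL-4 were present in both. Each condition gave 1 library, with 30877656 counts on named genes in the pathogenic library and 33470161 in the non-pathogenic library. No difference below has a replicate check, and the ranges given with folds are 95% counting intervals.

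The libraries differed by at least 2-fold at 445 of 10597 genes, or 4.20%. Of these, 238 were higher in the pathogenic library and 207 in the non-pathogenic library. At 4-fold the numbers were 38 and 29. Among the 4477 genes with a mean of at least 50 CPM, 17 were at least 2-fold higher in the pathogenic library and 24 in the non-pathogenic library. For most genes the libraries were close, with a log2 ratio between −0.63 and 0.70 for the central 90% of genes. The counts depend on the filter for low genes, as 96 and 101 genes passed 2-fold at a mean of at least 5 CPM and 1192 and 1136 with no filter.

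The gene ranked highest in the pathogenic library was Hic1, a transcriptional repressor (ENSMUSG00000043099, chromosome 11, 75164565 to 75169519), with 597 counts against 74 and an 8.61-fold ratio (6.84 to 11.3). Il12rb2, which encodes a chain of the IL-12 receptor, was 6.55-fold higher (5.31 to 8.31). Il2, the T cell growth factor gene, was 5.16-fold higher (4.46 to 6.05), and Gfi1, a zinc finger repressor, was 4.64-fold higher (4.21 to 5.14). The costimulatory receptor gene Cd226 was 5.80-fold higher (4.38 to 8.06). Cyp1b1, a cytochrome P450 gene, was 5.77-fold higher (4.55 to 7.55) by counts, with a smaller log2 ratio of 1.74 by FPKM than the 2.53 by counts. Scd2, a stearoyl-CoA desaturase gene, was 4.33-fold higher (4.15 to 4.53) at 10200 counts against 2544. Mid1ip1, a regulator of fatty acid synthesis, was 4.17-fold higher (3.56 to 4.96), and Gpr183, an oxysterol receptor gene, was 3.99-fold higher (3.49 to 4.59). H2-Q6 was 8.02-fold higher (6.17 to 10.9), but it is a class I gene with near-identical copies, and its value is uncertain.

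At the other end, the RNA-binding protein gene Igf2bp3 was 7.51-fold higher in the non-pathogenic library (5.76 to 10.2). Olfm2 was 5.14-fold higher there (3.89 to 7.13), Fam214b 4.82-fold (3.86 to 6.17) and the homeobox gene Lhx6 4.72-fold (3.64 to 6.34). The chemokine receptor gene Cxcr3 was 4.11-fold higher in the non-pathogenic library (3.19 to 5.48). Eng, which encodes the TGF-β co-receptor endoglin, was 4.03-fold higher (3.15 to 5.32), and Stard10 was 3.94-fold higher (3.20 to 4.94). Kif3c, a kinesin gene, had a log2 ratio of −1.91 by counts and −1.27 by FPKM. Hnrnpa3 had the lowest rank, with a log2 ratio of −3.07 by counts and −1.90 by FPKM, and like Apol9a, at −2.33, it has near-identical copies that make its value uncertain.

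A further 3 ranked genes lie over another gene on the same strand, and their values are uncertain because reads there can be assigned to either gene. Sept2 under the identifier ENSMUSG00000116048 was 6.38-fold higher in the pathogenic library, while the overlapping Sept2 identifier ENSMUSG00000026276 was 1.55-fold higher in the non-pathogenic library. The counts of the pair, when summed, gave a log2 ratio of −0.0078. Raver1 was 5.25-fold higher in the pathogenic library and its partner Gm38431 was 1.83-fold higher in the non-pathogenic library, with a summed log2 ratio of 0.16. Adnp was 7.17-fold higher in the non-pathogenic library, its partner Gm20716 was 1.99-fold higher in the pathogenic library, and their sum gave 0.032.

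The genes that define Th17 cells did not move together. Il17f, at 19634 counts in the non-pathogenic and 12180 in the pathogenic library, was 1.49-fold higher in the non-pathogenic library (1.46 to 1.53). Il17a was far less abundant, at 243 counts in the pathogenic and 207 in the non-pathogenic library, and was 1.27-fold higher in the pathogenic library (1.05 to 1.53). Rora, the gene for the transcription factor RORα, was 1.90-fold higher in the non-pathogenic library (1.82 to 1.99). Il23r, the receptor gene for IL-23, was 3.69-fold higher in the pathogenic library (3.01 to 4.61), and Il21 was 1.91-fold higher there (1.86 to 1.96). Il1r1 did not differ within counting error, at a log2 ratio of 0.0062 (−0.076 to 0.088), and neither did Il9, at 0.13 (−0.35 to 0.61). Of the 16 measured genes of the Th17 core list, 1 was at least 2-fold higher in the pathogenic library and none in the non-pathogenic library. The list's median log2 ratio of −0.065 lay inside the random range of −0.14 to 0.17, and its mean was 0.043, of the other sign. The 19 measured genes of the list of core genes to name, which were chosen for this comparison, had a median of −0.28, below the random range of −0.15 to 0.17, and a mean of −0.027.

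**Figure D1:**
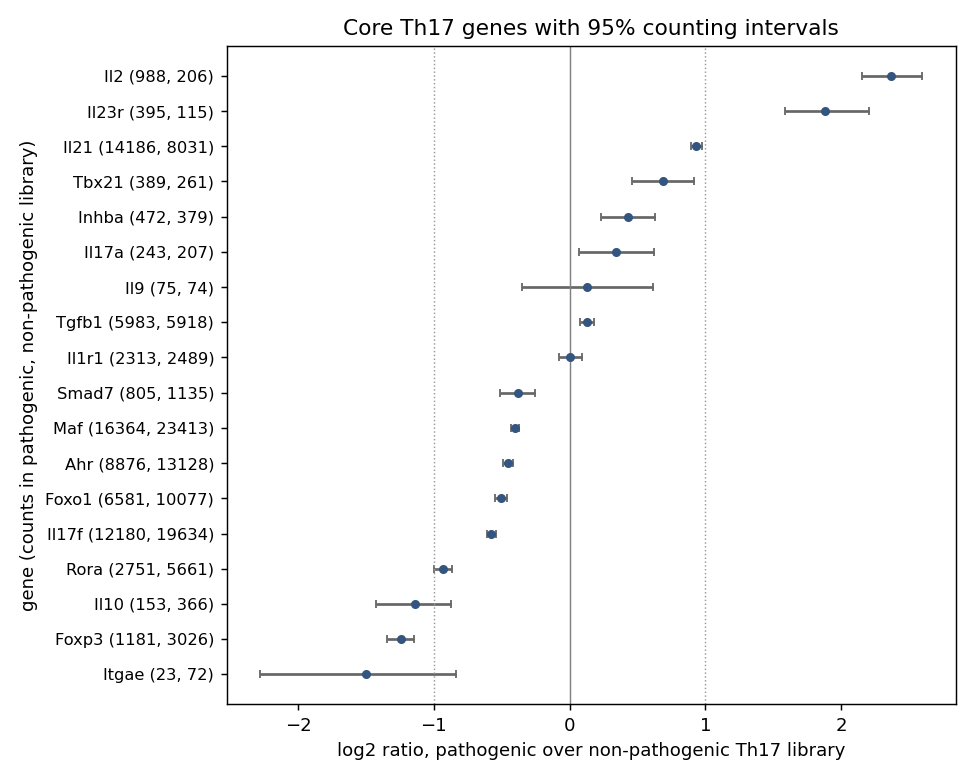
Log2 ratio of the pathogenic over the non-pathogenic Th17 library for 18 core genes with a mean of at least 1 CPM, with bars for 95% counting intervals, dotted lines at a 2-fold difference and raw counts beside each symbol. Il2 (2.37) and Il23r (1.88) lie above the upper dotted line, and Itgae, Foxp3 (−1.24) and Il10 (−1.14) lie below the lower one.

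Genes of the published pathogenic Th17 signature were higher in the pathogenic library as a group. Of 9 measured members, 7 had a ratio above 1 and 3 were at least 2-fold higher, namely Il23r, the chemokine gene Ccl3 at 3.22-fold (2.34 to 4.62), and Stat4, a transducer of IL-12 signals, at 2.48-fold (2.08 to 2.98). Ccl4 was 1.70-fold higher (1.45 to 1.99) and Tbx21, which encodes T-bet, 1.61-fold higher (1.37 to 1.89). With a transcript length and GC trend removed, the log2 ratio of Ccl4 was 0.42 in place of 0.76. The median log2 ratio was 0.69, at percentile 99.99 of random lists, whose range was −0.26 to 0.29. With no filter it was 1.04, or 0.94 with genes that had no count in 1 library at their bound. A further 7 members were under 1 CPM, among them Csf2, the GM-CSF gene, with 9 counts in the pathogenic and 21 in the non-pathogenic library, a difference within counting error. Gzmb had 17 and 4 counts, with a log2 ratio of 1.95 (0.58 to 4.23). Il22 had 8 and 0 counts, which is at least 2.88-fold higher in the pathogenic library against the floor of 3 counts. Its counting interval starts lower, at 1.84-fold. Ifng had no count in either library.

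The non-pathogenic signature list went the other way, with a median log2 ratio of −0.40 against a random range of −0.24 to 0.28, at percentile 0.31. Of its 7 members, 5 were lower in the pathogenic library. Il10, the gene of an anti-inflammatory cytokine, was 2.21-fold higher in the non-pathogenic library (1.83 to 2.69), the aryl hydrocarbon receptor gene Ahr 1.37-fold (1.33 to 1.41) and the transcription factor gene Maf 1.32-fold (1.30 to 1.35). The IL-6 receptor subunit gene Il6st had a log2 ratio of −0.59 (−0.62 to −0.55). Il1rn, the gene of the IL-1 receptor antagonist, was the exception of size, at 3.10-fold higher in the pathogenic library (2.72 to 3.57).

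Transcripts of the TGF-β/SMAD response were lower in the activin A culture than in the TGFβ1 culture. Of 12 measured members, 11 were below 1 and 3 were at least 2-fold higher in the non-pathogenic library. These were Spsb1 at 2.92-fold (2.66 to 3.23), the integrin gene Itgae at 2.82-fold (1.79 to 4.85) on 72 and 23 counts, and Ldlrad4, an inhibitor of SMAD signalling, at 2.33-fold (2.03 to 2.68). Smad7, a feedback inhibitor, was 1.30-fold higher in the non-pathogenic library (1.19 to 1.43). Bambi, a pseudoreceptor gene, was the member above 1, at 1.53-fold higher in the pathogenic library (1.05 to 2.29). The median of −0.42 lay below all 10000 random lists, whose range was −0.20 to 0.20.

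Genes of TGF-β and activin receptors went both ways. Acvr1 was 2.12-fold higher in the non-pathogenic library (1.69 to 2.71), the activin receptor gene Acvr2a 1.95-fold (1.84 to 2.07), Tgfbr1 1.74-fold (1.68 to 1.80) and Tgfbr2 1.52-fold (1.45 to 1.60). Tgfbr3 was higher in the pathogenic library, at a log2 ratio of 0.28 (0.17 to 0.40), and was picked after its value was seen, as was Acvr2b, under 1 CPM, at 0.91 (0.15 to 1.76). The ligand gene Inhba, which encodes the activin A subunit, was 1.34-fold higher in the pathogenic library (1.17 to 1.54), and Tgfb1 was 1.09-fold higher there (1.05 to 1.13), or 0.021 on the log2 scale with the length and GC trend removed. Tgfb3 had 12 counts in the non-pathogenic and 0 in the pathogenic library, at least 3.70-fold higher in the non-pathogenic library against the floor, with a counting interval that starts lower, at 2.57-fold. The median of the 11 measured components, −0.18, lay inside the random range of −0.19 to 0.18.

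Foxo1 (ENSMUSG00000044167, chromosome 3, 52268336 to 52353221), the factor named in the title of the series, had 6581 counts in the pathogenic and 10077 in the non-pathogenic library and was 1.42-fold higher in the non-pathogenic library (1.37 to 1.46). Of the 22 Foxo1-regulated and quiescence genes, which include Foxo1 itself, 16 were lower in the pathogenic library, with 1 past 2-fold. That gene was Ccng2, a cyclin gene of resting cells, at 2.17-fold higher in the non-pathogenic library (1.94 to 2.44). Klf2, which maintains naive T cell homing, was 1.89-fold higher there (1.68 to 2.13). Id3 and Il7r went the other way, at 1.91-fold (1.67 to 2.20) and 1.47-fold (1.24 to 1.74) higher in the pathogenic library. The list median was −0.17, at percentile 0.5 and below the random range of −0.13 to 0.14. Once the trend was removed it was −0.12, at percentile 2.53 and just inside the range.

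Foxp3, the regulatory T cell transcription factor gene, was 2.37-fold higher in the non-pathogenic library (2.22 to 2.54), at 3026 counts against 1181. Nt5e, which encodes the ectonucleotidase CD73, was 1.99-fold higher there (1.92 to 2.06). Of 16 regulatory T cell genes, 3 were at least 2-fold higher in the non-pathogenic library, namely Foxp3, Itgae and Il10, and none in the pathogenic library. A further 5 went the other way and were named after their values were seen, with log2 ratios of 0.82 (0.57 to 1.08) for Ikzf2, 0.68 for Tnfrsf18, 0.57 for Tnfrsf4, 0.42 for Ctla4 and 0.17 for Izumo1r. The median of −0.18 was below the random range of −0.17 to 0.18, at percentile 1.89, and with the trend removed it was −0.13, at percentile 5.94 and inside the range.

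Th1 genes were higher in the pathogenic library, with a median log2 ratio of 0.63 at percentile 99.98 over 8 measured genes, 5 of them above 1, and a random range of −0.30 to 0.30. Il12rb2 and Stat4 were past 2-fold, and Il12rb1 was 1.87-fold higher (1.79 to 1.95). Cxcr3, a chemokine receptor gene of Th1 cells, went against the list, as given above. The Th2 list rested on 4 measured genes and had a median of −0.49, below the random range of −0.34 to 0.35. Of these, Ccr8 was 2.00-fold higher in the non-pathogenic library (1.91 to 2.11), while Gata3, the Th2 master regulator gene, was 2.08-fold higher (1.23 to 3.80) on 46 and 20 counts. Leaving out Gata3 turned the median to 0.032.

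Of 9 measured follicular helper T cell genes, Cxcr5, the receptor that guides cells to B cell follicles, was 3.24-fold higher in the non-pathogenic library (3.02 to 3.48), and Bcl6 was 1.85-fold higher there (1.61 to 2.12). Cd200 was 2.56-fold higher in the pathogenic library (2.37 to 2.78). The list median of −0.11 lay inside the random range of −0.21 to 0.23 and was 0.22 without Cxcr5. Chemokines and their receptors had a median of −0.40, at percentile 0.12 against a random range of −0.24 to 0.26, with 4 of 14 genes at least 2-fold higher in the non-pathogenic library and 2 in the pathogenic library. The first set was Cxcr3, Cxcr5, Ccr8 and Cxcr4, the last at 2.32-fold (1.85 to 2.97). The median was −0.82 at a mean of at least 5 CPM, −0.25 with no filter and −0.64 with the trend removed.

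Cytokine genes had a median of 0.42, at percentile 99.88 against a random range of −0.21 to 0.24, with 9 of 12 measured genes above 1. Il2 was at least 2-fold higher in the pathogenic library and Il10 in the non-pathogenic library, and Ltb, the lymphotoxin β gene, was 1.73-fold higher in the pathogenic library (1.60 to 1.88). Of 16 T cell activation genes, Il2 and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, were past 2-fold, Tnfrsf9 at 2.95-fold (2.59 to 3.38). That list had a median of 0.12, at percentile 95.9 and inside the random range of −0.14 to 0.14. With the trend removed it was 0.16, at percentile 98.7 and above the range. The IL-6/STAT3 response list had a median of 0.26, above its range of −0.15 to 0.16, with the kinase gene Pim1 at 2.13-fold (2.03 to 2.24) higher in the pathogenic library. With the trend removed its median of 0.10 lay inside the range, at percentile 91.2. The 8 measured co-inhibitory receptor genes had a median of −0.10, inside the range of −0.22 to 0.25, and a mean of 0.036. Among them Btla was 1.52-fold higher in the pathogenic library (1.46 to 1.59) and Cd160 was 2.40-fold higher in the non-pathogenic library (1.62 to 3.76). The log2 ratio of Cd160 was −1.26 by counts and −2.11 by FPKM.

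Cell cycle genes were higher in the pathogenic library, at a median of 0.38 that lay above all 10000 random lists, whose range was −0.12 to 0.14. Of 19 genes, 17 were above 1 and none passed 2-fold. The mitotic kinase gene Plk1 was 1.91-fold higher (1.74 to 2.09), the cyclin B gene Ccnb1 1.87-fold (1.74 to 2.02), Cdc20 1.79-fold (1.65 to 1.93) and Aurkb 1.78-fold (1.66 to 1.90). Glycolysis and hypoxia genes had a median of 0.22, above the range of −0.12 to 0.12, with 16 of 19 genes above 1 and none past 2-fold. Hk2, a hexokinase gene, was 1.82-fold higher (1.75 to 1.90) and Mif 1.54-fold (1.51 to 1.58). With the trend removed the glycolysis median of 0.086 was inside the range, at percentile 92.3, and the log2 ratio of Mif, a short transcript, was 0.075 in place of 0.63. The Myc and ribosome biogenesis list and the cholesterol synthesis list had medians of 0.074 each, inside ranges of −0.12 to 0.14 and −0.15 to 0.13. Among their members, Lss, a sterol cyclase gene, was 1.47-fold higher in the pathogenic library (1.37 to 1.57) and Nip7, a ribosome biogenesis gene, 1.32-fold (1.26 to 1.38).

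Of 18 interferon-stimulated genes, 12 were under 1 CPM. The 6 measured genes had a median of 0.80, at percentile 99.99 against a random range of −0.30 to 0.33, led by Ly6a, the gene for Sca-1, at 2.43-fold higher in the pathogenic library (2.23 to 2.64). The median was 0.35 with the trend removed, at percentile 98.8, and 0.12 with no filter, or 0.48 without genes that had at most 3 counts in both libraries. Amino acid and ATF4 stress genes had a median of 0.28, above the range of −0.19 to 0.20, with 13 of 13 measured genes above 1. Atf3 was 5.56-fold higher (3.13 to 12.6) on 61 and 11 counts, and Trib3 was 1.52-fold higher (1.22 to 1.92). With the trend removed that median was 0.18, at percentile 97.0 and inside the range. Mitochondrially encoded transcripts took 2.80% of named-gene counts in the pathogenic and 3.44% in the non-pathogenic library. Their median was −0.27, below the range of −0.12 to 0.17, and members went both ways. mt-Nd5 was 1.48-fold higher in the non-pathogenic library (1.46 to 1.49), and mt-Nd3 was 1.41-fold higher in the pathogenic library (1.35 to 1.46). With the trend removed the median was −0.42 and all 13 genes were lower in the pathogenic library, with mt-Nd3 at a log2 ratio of −0.21. At 348 nucleotides and 33.0% GC, mt-Nd3 lies near the lowest values among measured genes, 204 nucleotides and 31.9%. A cubic fit is least certain at its ends, so the shared sign after trend removal is uncertain.

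**Figure D2:**
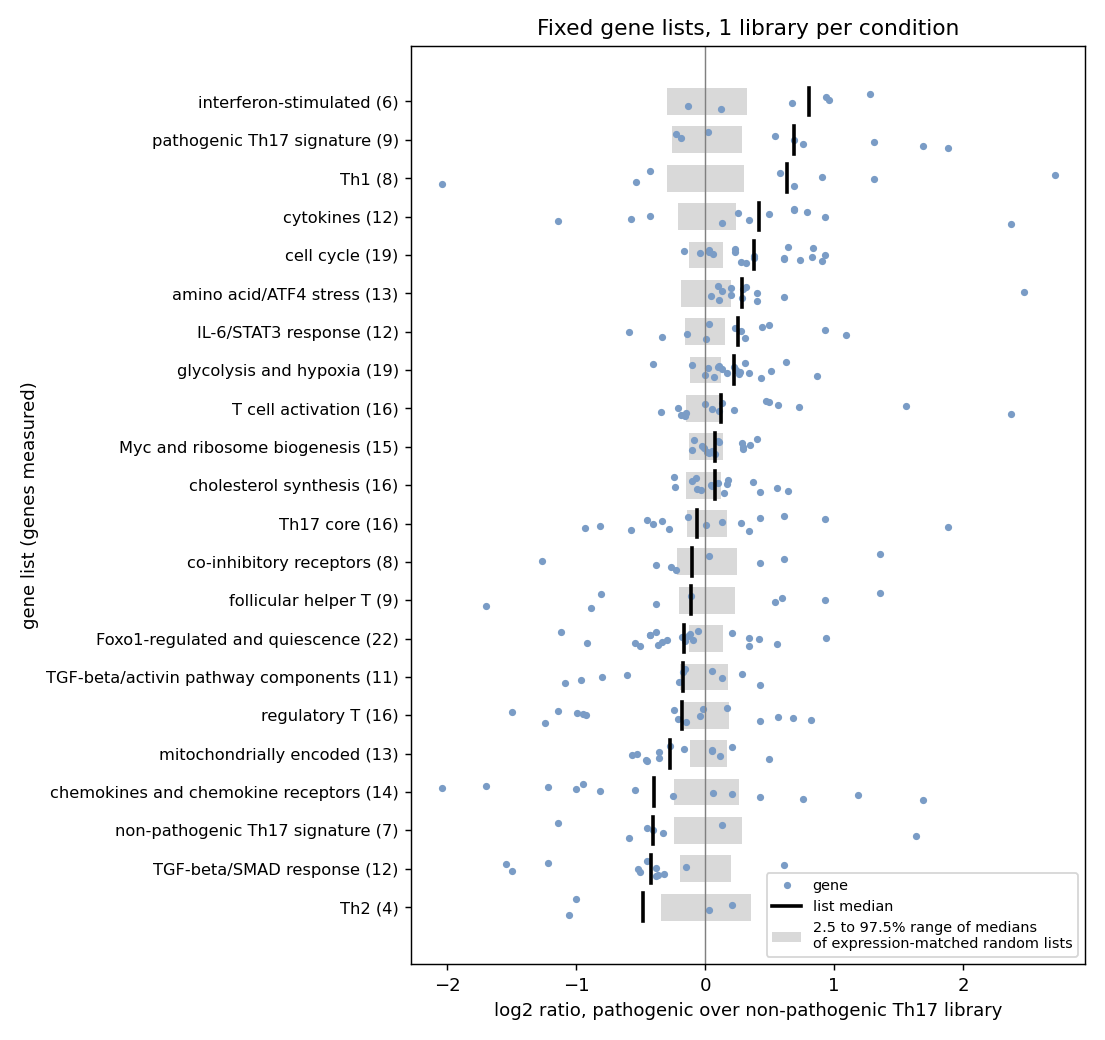
Log2 ratio of the pathogenic over the non-pathogenic Th17 library for each measured gene (dots) of 22 gene lists, with the list median (black line) and the range of medians of the central 95% of expression-matched random lists (grey). List medians lie above the range for 8 lists, below it for 7 and inside it for 7. Some genes, such as Il21, Il10 and Cxcr3, stand in several lists, so the lists are not independent.

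Of 48 markers of other cell types, 41 were under 1 CPM and 7 were above it, the highest being Pecam1 at a mean of 8.41 CPM. The B cell markers summed to 25 counts in the pathogenic and 6 in the non-pathogenic library, over 7 genes. The CD8 T cell markers summed to 111 and 167 counts, with Cd8b1 at 51 and 55 and Klrd1 at 47 and 98, which was 1.91-fold higher in the non-pathogenic library (1.35 to 2.79). The NK cell markers summed to 56 and 28 counts, mostly from the perforin gene Prf1, at 47 and 24 counts. The myeloid markers summed to 143 and 163 counts, mostly from Cd68, at 110 and 123 counts, and the dendritic cell markers to 115 and 93 counts, mostly from Cd74, at 94 and 61 counts. The erythroid markers summed to 76 and 118 counts, with Hbb-bs at 31 and 47. The stromal markers summed to 253 and 298 counts, mostly from Pecam1, at 253 and 289 counts.

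Short transcripts were shifted toward the pathogenic library. The 1060 genes with the shortest transcripts, up to 1311 nucleotides, had a median log2 ratio of 0.23, with 64 genes at least 2-fold higher in the pathogenic library and 15 in the non-pathogenic library. Across genes, which are not independent replicates, Spearman's rho of the log2 ratio was −0.14 with transcript length and 0.19 with GC percent. With the trend removed, 202 genes were at least 2-fold higher in the pathogenic library and 213 in the non-pathogenic library.

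**Figure D3:**
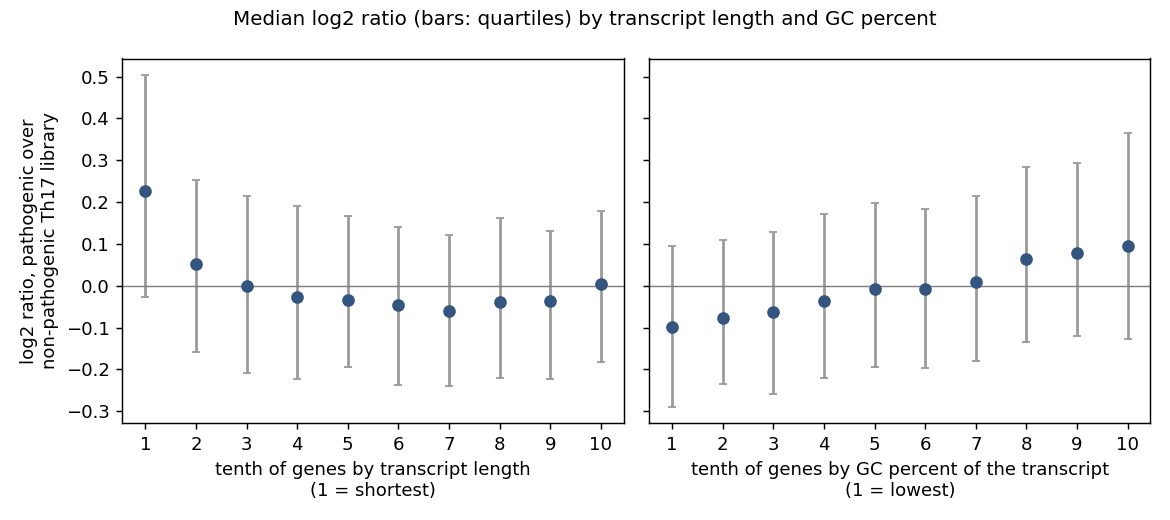
Median log2 ratio of the pathogenic over the non-pathogenic Th17 library, with bars from the lower to the upper quartile, for genes in 10 equal groups by length (left) and GC percent (right) of the longest protein-coding transcript. The shortest group has a median of 0.23, and the medians run from −0.099 at the lowest to 0.096 at the highest GC percent.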

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

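The tests of overlapping genes, of the list medians with the trend removed and of transcripts of other cell types were chosen after the results were seen. Features with no gene name, which the comparisons leave out, held 2.50% of counts in the pathogenic library (Wilson 95% interval 2.498 to 2.508) and 2.90% in the non-pathogenic library (2.895 to 2.906). The 3 largest of the 1646 features were 1.26-fold, 1.31-fold and 1.46-fold higher in the non-pathogenic library, and what they encode was not determined.

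Short transcripts were over-represented among genes higher in the pathogenic library. Without respiratory chain, ribosomal protein, mitochondrial ribosomal protein, histone and mitochondrially encoded genes, genes in the shortest of 10 length groups still had a median log2 ratio of 0.18 over 857 genes, with an order-statistic interval of 0.14 to 0.21. The prediction of a trend with transcript length, of the kind that RNA fragmentation or size selection may give, was therefore met. The shift lay mostly in the shortest group, as the next groups had medians of 0.052 and 0.00047. The test cannot separate a technical trend from higher expression of other short genes. Higher expression of the families left out remains open, because their 116 members with longer transcripts had a median of 0.056 with an interval of −0.021 to 0.13. Their 203 members in the shortest group had a median of 0.41. Over the 13 mitochondrially encoded genes the log2 ratio had a rho of −0.69 with length, across genes.

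Of the 445 genes at least 2-fold apart, 37 overlap another gene with a mean of at least 5 CPM on the same strand, and 34 of the 37 fell under 2-fold when summed with their partners, though a larger neighbour dilutes any ratio. In 48.6% of them, with an exact interval of 31.9 to 65.6%, the partner had the opposite sign, against 43.3% for the nearest same-strand neighbour of 386 genes with no overlap. This does not decide on shared reads, because 25 of the 37 partners had over 5 times the counts of the gene, and adding the gene's counts moved their log2 ratio by a median of only 0.050, though it turned the sign of Zfp7 and Zfp566. Among the other 12 the share was 66.7%, with an interval of 34.9 to 90.1%, which is too wide to decide. Some partners, such as Gm38394 and Gm38431, stand in several pairs, so the pairs are not independent and both intervals can be too narrow. For the Sept2, Raver1 and Adnp pairs a different assignment of the same reads in the libraries may account for both values, as could a change of transcript.

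The pathogenic Th17 list lay above and the TGF-β/SMAD response list below random lists. With the length and GC trend removed the medians were 0.62 and −0.40, both still outside the random range on the same side, which argues against that trend as the cause. Abundant transcripts of NK, CD8 and myeloid cells (Nkg7, Tyrobp, Lyz2, Cd8a and S100a9) summed to 0.26 CPM more in the pathogenic library, at 1.03 against 0.778 CPM. The full lists, with Prf1, Klre1 and Fcer1g, differed by 0.973, −1.41 and −0.253 CPM in turn. The CD8 and myeloid sums were thus not higher in the pathogenic library, which argues against a large excess of those cells there. The lower CD8 sum came from Klrd1, at 1.52 CPM in the pathogenic against 2.93 in the non-pathogenic library, while Cd8b1 was at 1.65 in both. The NK sum was low but higher in the pathogenic library, at 1.81 against 0.838 CPM, mostly from Prf1. The B cell and dendritic cell sums, outside the test, were also higher there, at 0.808 against 0.180 and 3.72 against 2.78 CPM. The erythroid and stromal sums were lower there. A small excess of NK, B or dendritic cells is therefore not excluded. A difference between any 2 cultures, whatever the cytokines, cannot be told apart from an effect of the cytokines with 1 library per condition. An effect of activin A in place of TGFβ1, the difference that the design names, stays open and untested.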

How the results depend on the processing

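The trend removal, the inclusion of features with no gene name and the omission of overlapping genes were chosen after the data were examined. The numbers of genes at least 2-fold higher in the pathogenic and non-pathogenic libraries, 238 and 207, became 1192 and 1136 with no filter, 96 and 101 at a mean of at least 5 CPM, and 95 and 66 with log2(FPKM + 1), which shrinks low genes. They became 763 and 610 at a fold limit of 1.5, 38 and 29 at 4, and 119 and 103 where the interval had to lie wholly past 2-fold, as a looser or stricter limit must give. Under the other 8 settings they stayed within 1.5 times. The Th2 list reversed, from −0.49 to 0.032 with no filter, at a mean of at least 5 CPM, without its member of the largest ratio and without overlapping genes, and to 0.035 with unnamed features kept. Gata3, on 20 and 46 counts, leaves the list under these settings except with no filter, where genes of at most 5 counts enter. No other list median outside the random range changed sign under the alternatives run. Its place against the range was less stable. With the trend removed, the Foxo1, regulatory T cell, glycolysis, IL-6/STAT3 and ATF4 stress medians fell inside the range. The T cell activation median moved out of it. Of 939 values of named genes under the alternatives, 87 moved out of the counting interval, 44 of them with log2(FPKM + 1) and 30 with the trend removed, and those at least 2-fold apart kept their sign. The sign turned for mt-Nd3 with the trend removed, from 0.49 to −0.21, and for Il1r1, Il4ra, Il9, Cd8b1 and Cd68, whose log2 ratios were at most 0.13 from 0 before the change. Other scalings shifted all ratios by 0.0043 or −0.0019 on the log2 scale. The planned fit for several columns per sample was not run, because each sample has 1 column. No paired analysis was possible because each condition has 1 library. Depth limits genes such as Csf2, Il22, Gzmb and Tgfb3, with at most 21 counts in a library.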

Other observations

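The tests of G2/M, LXR and AhR genes were written before those lists were measured, on patterns already seen. Outside the lists described so far, genes of G2 and mitosis were higher in the pathogenic library in 30 of 33 cases, with a median log2 ratio of 0.45 against a random range of −0.12 to 0.10. Kif2c, a mitotic kinesin gene, had a log2 ratio of 0.94, Cdca3 0.91 and Cenpf 0.81, while Psrc1, a spindle gene, went the other way at −1.24. Genes of S phase were higher in 28 of 35 cases with a smaller median of 0.13, against a range of −0.10 to 0.09. The thymidylate synthase gene Tyms had a log2 ratio of 0.57. These genes were picked here as examples after their values were seen.

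Neighbouring cytokine and receptor genes were higher in the same library at 2 loci, a point noticed after the values were seen and not tested. Il12rb2 (chromosome 6, 67291318 to 67376188) lies beside Il23r (67422932 to 67491855), and both were higher in the pathogenic library, by 6.55-fold and 3.69-fold. Il2 (chromosome 3, 37120523 to 37125959) lies near Il21 (37222759 to 37232636), and both were higher there, by 5.16-fold and 1.91-fold. Il17a and Il17f, neighbours on chromosome 1, went opposite ways, at log2 ratios of 0.34 and −0.58.

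A first hypothesis was that the pathogenic library holds a larger share of G2/M transcripts. With the length and GC trend removed, the G2/M median exceeded the S phase median by 0.32, past the 0.25 set in advance. The prediction was met, but the pattern had already been seen in cell cycle genes of the same libraries. The result extends that pattern to further genes and is not an independent test of it. Whether more cells were in G2/M was not measured, and with 1 library per condition the difference may be one between cultures.

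A second hypothesis was that LXR and fatty acid synthesis genes in general are higher in the pathogenic library, as Scd2 and Mid1ip1 are. Scd1, named after its values were seen, had 110 and 2 counts, with a ratio of 39.5-fold and an interval of 16.1 to 497. The other 15 measured genes had a median of 0.16, at percentile 94.8 and inside the random range of −0.19 to 0.20, with an order-statistic interval of −0.048 to 0.39. A median inside the range was set in advance to count against it, but the interval reaches past the upper end of the range, so the test was read, after the values were seen, as not deciding. Fads2 (1.43), Abcg1 (1.27) and Abca1 (1.26) were past 2-fold on the log2 scale, while Fasn (0.16) and Acly (0.12) were not.

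The last hypothesis was that AhR target genes in general are higher in the pathogenic library, as Cyp1b1 is although Ahr is lower. The 4 measured targets of 8 had a median of −0.11, inside a random range of −0.39 to 0.44, which was set in advance to count against it. Their values ran from −0.19 to 0.38, with 1 above 0 and 3 below. All lay below the upper end of the range, which argues against a shift of that size in the measured targets. With 4 genes the range is wide, so the test cannot decide on a smaller shift. Cyp1a1, the best known target, had a log2 ratio of −0.19, and Nqo1 had 15 and 0 counts, at least 5.40-fold higher in the pathogenic library against the floor of 3 counts, with a counting interval that starts lower, at 3.88-fold.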
